A study of Homo sapiens with 8 samples.

How the data were processed

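Left ventricular tissue of 8 explanted human hearts was measured on Affymetrix arrays, 1 array per heart, with 4 hearts in ischemic end-stage failure and 4 non-failing hearts, grouped by their sample titles. Per the labels' protocols, tissue was frozen quickly after explant, RNA was isolated with a column kit, its integrity was checked on a Bioanalyzer against a minimum score, and biotin-labelled RNA was prepared by linear amplification. The submitters' processing notes name RMA, affy and limma, with no versions, and further steps are not given in the sources used here. RMA corrects background, normalizes the arrays to a common distribution of signals by quantiles and summarises the probes of each probe set, so a shift common to most genes would not be seen in its values. The deposited values of 54675 probe sets were taken to be log2 signals, from their range and from RMA, per the submitters' processing notes. The amplification runs from the 3′ end of the RNA, so signal far from that end depends on the integrity of the RNA and on the length of the amplified product.

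No normalization was added to the deposited values. The file used here holds no detection calls, so signal over background was not assessed. Probe sets were named through the platform annotation given for this work, with symbols updated by Entrez ID against a gene table of assembly GRCh38.p14, from which no coordinates were used. The 62 control probe sets and those of XIST and of genes on chromosome Y were left out of the tests, and 54500 probe sets remained. Of these, 41014 had 1 gene, of which 40960 matched the gene table by Entrez ID, 1765 had several genes and 11721 were unnamed here. Each of 19732 genes was represented by the probe set with exactly 1 gene symbol and the highest mean signal over the 8 arrays. Genes with near-identical copies, such as MYH6 and MYH7, and probe sets with names ending in _x_at or _s_at can take signal from more than 1 gene, and their values are less certain.

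Failing and non-failing hearts were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, group as the only term, all 8 arrays), with an adjusted p under 0.05 after Benjamini-Hochberg adjustment over the genes tested. The same fit was run on all 54500 probe sets. No filter on low signal was used. The moderated variance had 3.54 prior degrees of freedom. The median difference of all genes was 0.0088 on the log2 scale. On 5 simulated data sets with the means and moderated variances of the 19732 genes and 200 changed genes, the procedure recovered 91% of 2-fold and 99.2% of 4-fold changes, with 4.41% false calls. In the same simulations without the 200 changed genes, limma's list test camera called 5 of 5 lists with every member shifted, at an unadjusted p under 0.05. The noise was independent between genes, so the simulations do not cover correlated genes or a difference in RNA quality between groups. Moderated variances are drawn towards a common value, so the most variable genes were simulated with less noise than they had, and their recovery may be overstated.

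A set of 33 gene lists with 652 distinct genes was fixed before the data were examined, and 597 of the genes were measured. They were natriuretic peptide and stress genes, sarcomere, calcium handling, ion channels and gap junctions, collagens and matrix, basement membrane, matrix proteases, WNT and TGF-beta signalling, fatty acid oxidation, oxidative phosphorylation, TCA cycle, glucose use, adrenergic and renin-angiotensin signalling, immediate early genes, hypoxia, heat shock, cytokines, interferon response, complement and coagulation, apoptosis and cell cycle, and markers of cardiomyocytes, fibroblasts, endothelium, smooth muscle, macrophages, neutrophils, lymphocytes, mast cells, adipocytes, Schwann cells, red blood cells, mesothelium and atrial myocardium. Some genes stand in more than 1 list, and the markers describe bulk tissue, in which no cell was classified. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Beside it stand camera with an estimated correlation, fry, and an exact two-sided permutation test of the list mean per heart over 70 assignments of the 8 hearts, whose smallest possible p is 0.0286.

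Genes were named by a rule fixed before the data were examined. It took the 10 largest increases and the 10 largest decreases among genes past the threshold without overlap between the groups, up to 4 members past the threshold from each list or, where none passed, the 2 of smallest p, and always NPPA, NPPB, MYH6, MYH7, ACTA1 and ATP2A2. Genes of common inherited presence or absence and highly polymorphic genes were left out of the naming, which concerned 2 of the changed genes. The rule gave 75 named genes. C1QC was added after its value was seen.

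RNA quality was read from the 3′, middle and 5′ control probe sets of GAPDH and ACTB, as differences of log2 signals per array, and compared by exact two-sided permutation. Alternatives fixed before the data were examined were repeated quantile normalization, centring on array medians, filters on signal at a mean log2 signal of 5 or at the upper part of the genes, eBayes with trend and robust prior, array weights, other choices of probe set, an adjusted p of 0.01, a minimum of 1.5-fold, the replicate number as a block, the GAPDH control as a covariate, and leaving out each heart in turn. Further alternatives, added after seeing the data, were the mean of the GAPDH and ACTB controls as a covariate, leaving out non-failing heart 4 and failing heart 1 together and, for the gene lists, the GAPDH control as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.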

Results

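Gene expression was measured in left ventricular tissue from 8 explanted adult human hearts, 4 with end-stage failure of ischemic origin and 4 non-failing. Each heart was read on 1 Affymetrix array, and the labels call the hearts biological replicates. The question asked of the comparison was which genes differ between failing and non-failing ventricles. The deposited log2 signals of 54675 probe sets had array medians between 5.07 and 5.14, and 19732 genes were tested, each through 1 probe set. The number of arrays, 4 per group, limits the precision of every value below, and differences are failing minus non-failing hearts.

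In the failing ventricles, 6 of 14 macrophage marker genes fell and 2 of 23 interferon response genes rose. CD163, the macrophage receptor for haptoglobin-bound hemoglobin, fell by 2.93 on the log2 scale (7.62-fold, SE 0.27, n = 4 hearts per group, limma with Benjamini-Hochberg adjustment, adjusted p = 0.00506), and was at -0.69 (limma adjusted p = 0.0486) without probe sets whose names end in _x_at or _s_at, which may cross-hybridize. LYVE1, a hyaluronan receptor of lymphatic endothelium and resident macrophages, fell by 2.52 (SE 0.25), and VSIG4, a complement receptor of tissue macrophages, fell by 2.20 (SE 0.14, limma adjusted p = 0.000794). MX1, an interferon-induced GTPase with antiviral activity, rose by 1.00 (2.00-fold, SE 0.14, limma adjusted p = 0.0278), and PSMB9, a subunit of the immunoproteasome, rose by 0.80 (SE 0.13). For each of these genes all 4 failing hearts lay on one side of all 4 non-failing hearts.

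In all, limma called 79 of the 19732 genes changed, 28 higher and 51 lower in failing hearts, at a Benjamini-Hochberg adjusted p under 0.05. Fold changes of the 79 genes ran from 1.43 to 18.8, with 9 genes at least 2-fold higher and 31 at least 2-fold lower. The failing and non-failing values did not overlap for any of the 79 genes. Over all tested genes, 1617 (8.19%) had no overlap between the groups, where chance gives 2.86%. At an unadjusted p under 0.05 there were 2687 genes, where chance gives 987 on average. Other splits of the 8 hearts into 4 and 4 gave 343 to 1933 genes. On the level of probe sets, 105 of 54500 changed, 49 higher and 56 lower. The changed genes had 96 further probe sets, of which 86 moved in the same direction, 53 of them at an unadjusted p under 0.05, and 0 moved in the opposite direction at that level.

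Among genes past the threshold the largest decrease belonged to CYP4B1, a cytochrome P450 of the fatty acid hydroxylase family, which went from 10.65 ± 0.60 (SD, n = 4) in non-failing to 6.42 ± 1.67 in failing hearts, 18.8-fold lower (limma adjusted p = 0.0451). Its other probe set was at -1.45, and over 23 alternatives CYP4B1 ran from -4.71 to -2.84, past the threshold in 13. SERPINA3, an acute phase inhibitor of serine proteases, fell by 2.22 (SE 0.37), passed under 10 of 23 alternatives and ran from -3.35 to -1.99 over them. FKBP5, a co-chaperone of the glucocorticoid receptor, fell by 1.96 (SE 0.21, limma adjusted p = 0.00862), from 12.30 ± 0.12 in non-failing to 10.35 ± 0.48 in failing hearts. MS4A4A, a membrane protein of macrophages, fell by 1.93 (SE 0.31), F13A1, the catalytic subunit of coagulation factor XIII, fell by 1.83 (SE 0.29), and MRC1, the mannose receptor, fell by 1.80 (SE 0.24). CPM, the membrane-bound carboxypeptidase M, fell by 1.74 (SE 0.28).

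Among genes past the threshold the largest increase belonged to CXCL2, a chemokine that attracts neutrophils, which went from 6.52 ± 0.71 (SD, n = 4) to 8.63 ± 0.30, 4.29-fold higher (limma adjusted p = 0.0296). ITIH5, a hyaluronan-binding protein of the inter-alpha-trypsin inhibitor family, rose by 1.42 (SE 0.21), and ANKRD34C by 1.41 (SE 0.17). The signal of ANKRD34C was low, 3.94 ± 0.21 in non-failing and 5.35 ± 0.31 in failing hearts, and signal over background was not assessed. EXT1, a glycosyltransferase that elongates heparan sulfate chains, rose by 1.22 (SE 0.14, limma adjusted p = 0.0103), and DPYSL3 by 1.22 (SE 0.15). KCNN3, a calcium-activated potassium channel of small conductance, rose by 1.16 (SE 0.15), TNNT1, the troponin T of slow skeletal muscle, by 1.08 (SE 0.16), ATP2B4, a calcium pump of the plasma membrane, by 1.03 (SE 0.13), and P2RY8, a G protein-coupled receptor, by 1.02 (SE 0.16). Without probe sets that may cross-hybridize DPYSL3 turned to -0.07 (limma adjusted p = 0.86), CXCL2 was 0.51, ATP2B4 0.36 and MS4A4A -1.35, none of them past the threshold. These values come from other probe sets of the same genes. A further DPYSL3 probe set, which may also cross-hybridize, was at 1.03. With the mean of all probe sets of a gene KCNN3 was at 0.54 and DPYSL3 at 0.73, not past the threshold. After repeated quantile normalization ATP2B4 was at 0.40, also not past it. The probe set of each gene was chosen again after that step, and the other ATP2B4 probe sets were at 0.36 and 0.32 as deposited. The lower value therefore need not come from the normalization.

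**Figure D1:**
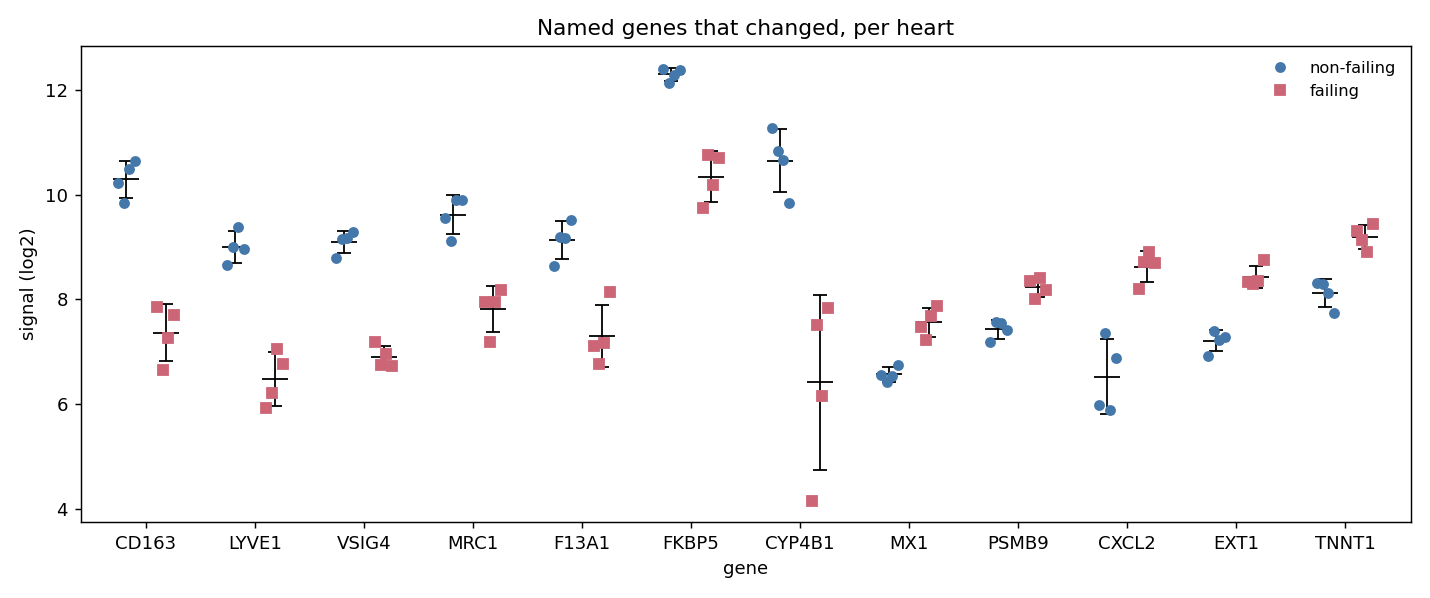
Signal (log2, vertical axis) of 12 genes that changed, with 1 point per heart, 4 non-failing (circles) and 4 failing (squares), and black bars for the mean ± SD. For each gene shown, the failing hearts lay wholly below or wholly above the non-failing hearts, and CYP4B1 had the widest spread among failing hearts (SD 1.67).

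Of the 14 measured members of the macrophage list, 6 fell (CD163, LYVE1, VSIG4, F13A1, MRC1 and C1QC), 0 rose and 8 did not pass, and 8 fell when adjusted over the list alone. The mean of the list was 6.84 ± 0.16 (SD, n = 4) in failing and 7.95 ± 0.21 in non-failing hearts, a difference of -1.10 without overlap between the groups (exact two-sided permutation p = 0.0286, the smallest possible with 4 against 4; 0.189 after adjustment over 33 lists). limma's camera with a preset correlation of 0.01 gave an adjusted p = 3.34e-13 for the list. Its adjusted p = 0.117 with an estimated correlation did not pass, whereas limma's fry gave an adjusted p = 0.00337. In the same hearts the RNA control of GAPDH, its 3′ minus 5′ signal, differed between the groups by -1.60.

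Of the 23 measured interferon response genes, 2 rose (MX1 and PSMB9), 0 fell and 21 did not pass, although 11 rose when adjusted over the list alone and 22 of the 23 differences were positive. The mean of the list was 7.58 ± 0.35 in failing and 6.97 ± 0.21 in non-failing hearts (SD, n = 4), a difference of 0.60 without overlap (exact two-sided permutation p = 0.0286, adjusted over 33 lists 0.189). limma's camera gave an adjusted p = 6.63e-11, and an adjusted p = 0.413 with an estimated correlation. With the GAPDH 3′ minus 5′ control as a covariate, an alternative added after seeing the data, the mean difference of the list was 0.99.

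Collagen and matrix genes were spread widely within both groups. Of 40 measured members, 0 rose or fell over all genes tested and 2 rose when adjusted over the list alone, COL6A2 (0.48) and FBLN1 (0.76). The mean difference of 0.40 passed limma's camera (adjusted p = 0.00638) but not with an estimated correlation (adjusted p = 0.70). The list mean of 1 non-failing heart, number 4, was 9.81, against 8.14 to 8.32 in the other 3 non-failing hearts and a mean of 9.02 ± 0.46 (SD, n = 4) in failing hearts. Without that heart the mean difference was 0.80 (camera adjusted p = 4.79e-13), and camera no longer passed without failing heart 1 (0.19, adjusted p = 0.276), non-failing heart 1 (0.26) or non-failing heart 3 (0.24). With the GAPDH 3′ minus 5′ control as a covariate the mean difference was 0.95 for collagens and matrix and 0.92 for fibroblast markers. The fibroblast markers had a mean difference of 0.41, with 0 of 12 past the threshold over all genes, 2 higher adjusted over the list alone, among them DPT (0.91), a dermatopontin of the matrix, and limma's camera adjusted p = 0.0385 (adjusted p = 0.498 with an estimated correlation). Their mean difference was 0.67 without non-failing heart 4, and camera no longer passed without non-failing heart 1 (0.30), non-failing heart 3 (0.26), failing heart 1 (0.29) or failing heart 2 (0.45).

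**Figure D2:**
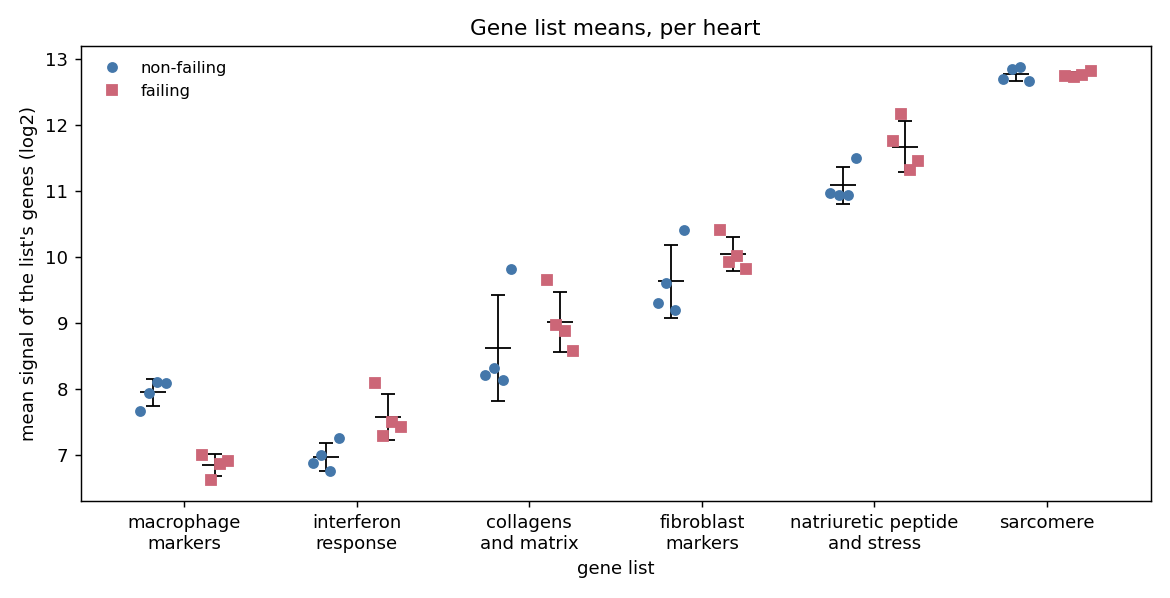
Mean log2 signal (vertical axis) of the genes of 6 lists, with 1 point per heart, 4 non-failing (circles) and 4 failing (squares), and black bars for the mean ± SD. The groups did not overlap for macrophage markers (difference -1.10) and interferon response genes (difference 0.60), and did overlap for the other 4 lists shown.

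Genes widely used as markers of heart failure did not pass over all genes tested. The natriuretic peptides NPPA and NPPB were 1.32 (SE 0.66) and 1.94 (SE 0.87) higher in failing hearts, with limma adjusted p = 0.421 and 0.369. MYH6, the fast alpha isoform of cardiac myosin, was at -1.95 (SE 0.45, limma adjusted p = 0.105), while MYH7, the slow beta isoform, was at 0.16. ACTA1, skeletal muscle actin, was at 0.48 and ATP2A2, the calcium pump of the sarcoplasmic reticulum, at -0.03. Of the 11 measured natriuretic peptide and stress genes, 0 passed over all genes and 0 adjusted over the list alone. Their mean difference of 0.59 passed limma's camera with an adjusted p = 0.0387, and had an adjusted p = 0.432 with an estimated correlation. The list mean of non-failing heart 4 was 11.50 against 10.93 to 10.96 in the other non-failing hearts, and without it the mean difference was 0.73. Camera no longer passed without non-failing heart 1 (0.55), non-failing heart 3 (0.54), failing heart 1 (0.56), failing heart 2 (0.42) or failing heart 4 (0.66), nor with the GAPDH 3′ minus 5′ control as a covariate (0.50, adjusted p = 0.273).

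Muscle and metabolic gene groups held few changed members. Among 18 sarcomere genes 0 passed over all genes, and 1 was higher and 1 lower adjusted over the list alone, which were ACTN2 (0.30) and MYH6 (camera adjusted p = 0.514). Among 19 calcium handling genes 1 rose, ATP2B4, and 1 fell, FKBP1B (-1.37), a binding partner of the ryanodine receptor, with the same counts adjusted over the list alone (camera adjusted p = 0.46). FKBP1B passed under 7 of 21 alternatives. Among 18 ion channel and gap junction genes 1 rose, KCNN3, also adjusted over the list alone (camera adjusted p = 0.257). None of 45 oxidative phosphorylation genes passed, 0 adjusted over the list alone, with NDUFA10 at 0.91 and SDHC at 0.74, which turned to -0.06 without probe sets that may cross-hybridize (camera adjusted p = 0.955). None of 27 fatty acid oxidation genes passed, 0 adjusted over the list alone, with ACSL1 at -0.56 and ECHS1 at 0.39 (camera adjusted p = 0.454). The mean difference of the fatty acid oxidation list was -0.05, and camera passed downward without non-failing heart 4 (-0.19), without that heart and failing heart 1 (-0.16) and with the GAPDH control as a covariate (-0.31). Of 14 TCA cycle genes 0 passed, and 2 were higher adjusted over the list alone, IDH3G (0.56) and DLST (0.41) (camera adjusted p = 0.259).

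Among 26 genes of glucose use, SLC2A1, the insulin-independent glucose transporter, fell by 0.84 (SE 0.13, limma adjusted p = 0.0316) and 25 did not pass, and 1 was higher and 2 lower adjusted over the list alone. Without probe sets that may cross-hybridize SLC2A1 was at -0.16 (limma adjusted p = 0.592), and it passed under 9 of 23 alternatives. The list as a whole went the other way, with a mean difference of 0.18 and limma's camera adjusted p = 0.0385 (adjusted p = 0.696 with an estimated correlation). With the GAPDH 3′ minus 5′ control as a covariate its mean difference turned to -0.11, and camera no longer passed without non-failing heart 1 (0.14), non-failing heart 4 (0.14), failing heart 1 (0.21) or failing heart 2 (0.13). Among 27 adrenergic and renin-angiotensin genes 0 passed over all genes, and 5 were higher and 1 lower adjusted over the list alone, with APLNR, the apelin receptor, at 1.71 and AGTR1, the type 1 angiotensin receptor, at -1.78. The mean difference of that list was 0.23, with limma's camera adjusted p = 0.0385 and an adjusted p = 0.425 with an estimated correlation. Camera no longer passed for it without non-failing heart 1 (0.20), non-failing heart 4 (0.22), failing heart 1 (0.19) or failing heart 4 (0.20), nor with the covariate (0.22).

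Of 31 basement membrane genes 1 rose, FREM1 (0.76), and 1 fell, NID1 (-1.32), the linker protein nidogen, while 2 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.129). The signal of FREM1 was low, 4.29 in non-failing and 5.05 in failing hearts. The mean difference of the basement membrane list was 0.11. Camera passed upward for it without non-failing heart 4 (0.20), without failing heart 3 (0.17) and with the GAPDH control as a covariate (0.33). NID1 was at -0.75 with the mean of all its probe sets. Of 19 matrix proteases and inhibitors 1 fell, TIMP4 (-1.51), a metalloproteinase inhibitor abundant in heart, and 3 were lower adjusted over the list alone (camera adjusted p = 0.46). Of 27 WNT and TGF-beta genes 0 passed over all genes and 3 were higher adjusted over the list alone, with FRZB, a secreted WNT antagonist, at 1.64 (limma adjusted p = 0.053) and TGFB2 at 1.42 (camera adjusted p = 0.259). Of 26 immediate early genes 0 passed and 1 was higher adjusted over the list alone, with EGR1 at 1.82 and IER2 at 0.71 (camera adjusted p = 0.625). Of 21 hypoxia genes 0 passed, and 1 was higher and 1 lower adjusted over the list alone, with HIF3A at -1.44 and NDRG1 at 0.43 (camera adjusted p = 0.289). Of 23 heat shock and unfolded protein genes 0 passed and 1 was lower adjusted over the list alone, with ATF4 at -0.48 and HSPB1 at 0.47 (camera adjusted p = 0.772). Of 21 apoptosis and cell cycle genes 0 passed and 1 was higher adjusted over the list alone, with CCND1 at 0.52 and GADD45A at 0.52 (camera adjusted p = 0.79).

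Of 27 cytokine and acute phase genes 1 rose, CXCL2, and 2 fell, SERPINA3 and IL1RL1 (-1.13), the receptor of interleukin 33, while 3 were higher and 5 lower adjusted over the list alone (camera adjusted p = 0.557). Of 19 complement and coagulation genes 2 fell, F13A1 and TFPI (-0.91), the inhibitor of the tissue factor pathway, and 1 was higher and 3 lower adjusted over the list alone (camera adjusted p = 0.772). TFPI passed under 7 of 23 alternatives, and was at -0.39 on the probe set with the largest interquartile range, where it did not pass.

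Of 15 lymphocyte markers 0 passed over all genes and 1 was higher adjusted over the list alone, CCL5 (0.81), with GZMA, a cytotoxic granule protease, at 0.73. Their mean difference of 0.21 passed limma's camera (adjusted p = 0.0495), with an adjusted p = 0.432 with an estimated correlation, and of the fits with 1 heart left out it passed only the one without failing heart 2 (0.26). The mean signal of the list was low, 4.85 in failing and 4.65 in non-failing hearts, and signal over background was not assessed. Of 6 red blood cell markers 0 passed over all genes and 2 were higher adjusted over the list alone, HBB (3.26, SE 0.79) and HBD (0.32). The mean difference was 0.67 but the median 0.18, so HBB carried much of the mean, which ran from 0.45 to 1.18 over 16 alternatives. For this list limma's camera gave an adjusted p = 0.0385, and an adjusted p = 0.432 with an estimated correlation. HBB turned to -0.12 without probe sets that may cross-hybridize, and the red blood cell list did not pass without non-failing heart 3 (0.75), non-failing heart 4 (0.66), failing heart 2 (0.70) or failing heart 4 (0.61), nor with the GAPDH covariate (0.45). Of 12 smooth muscle and pericyte markers 1 rose, NOTCH3 (0.73), a receptor of mural cells, also adjusted over the list alone (camera adjusted p = 0.525), but NOTCH3 was at 0.46 with the mean of its probe sets and did not pass. Of 10 atrial markers 0 passed over all genes and 1 was higher adjusted over the list alone, SLN (1.98), sarcolipin, with KCNA5 at 0.77 (camera adjusted p = 0.129), and the atrial list passed without failing heart 3 (0.55). Of 11 cardiomyocyte markers 0 passed over all genes, and 1 was higher and 1 lower adjusted over the list alone (camera adjusted p = 0.46). None of 12 endothelial markers passed, 0 adjusted over the list alone, with PECAM1 at -0.67 and CLDN5 at 0.44 (camera adjusted p = 0.496). The same counts of 0 and 0 held for 11 neutrophil and monocyte markers, with S100A9 at -1.03 and CXCR2 at 0.47 (camera adjusted p = 0.909), and for 9 mast cell markers, with HPGDS at 0.38 and CTSG at 0.29 (camera adjusted p = 0.454). They held too for 9 adipocyte markers, with PLIN4 at 0.37 and LIPE at 0.43 (camera adjusted p = 0.772), 8 Schwann and neural markers, with CDH19 at -0.44 and SOX10 at 0.22 (camera adjusted p = 0.46), and 10 mesothelial markers, with KRT18 at 0.26 and KRT8 at 0.38 (camera adjusted p = 0.454).

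In all, 9 of the 33 lists passed limma's camera with the preset correlation after Benjamini-Hochberg adjustment, 8 higher and 1 lower in failing hearts. With an estimated correlation 0 lists passed camera (3 at an unadjusted p under 0.05), after adjustment of the exact permutation p 0 passed (5 at an unadjusted p under 0.05), and fry, which asks whether a list's genes move on balance in one direction, passed 1, the macrophage markers. With 1 heart left out at a time, the macrophage and interferon lists passed camera in 8 of 8 fits, collagens and matrix in 5, glucose use, adrenergic genes, fibroblast and red blood cell markers in 4 each, natriuretic peptide and stress genes in 3 and lymphocyte markers in 1. With the GAPDH control as a covariate, an alternative added after seeing the data, 12 lists passed, 5 of them shared with the 9. The others were, upward, basement membrane (0.33), immediate early genes (0.31) and endothelial markers (0.24) and, downward, fatty acid oxidation (-0.31), oxidative phosphorylation (-0.10), smooth muscle and pericyte markers (-0.43) and adipocyte markers (-0.93). For several lists the mean, the median and the direction of camera differed in sign. Mean and median were -0.01 and 0.09 for sarcomere genes, -0.07 and 0.09 for cardiomyocyte markers and -0.05 and 0.03 for neutrophil and monocyte markers, with camera directed upward. They were 0.05 and -0.01 for oxidative phosphorylation genes, 0.11 and -0.0012 for immediate early genes, -0.05 and -0.02 for apoptosis and cell cycle genes and -0.11 and -0.02 for adipocyte markers, again with camera directed upward. For complement and coagulation genes they were -0.06 and 0.10, with camera directed downward.

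The RNA controls differed between the groups. The 3′ control probe set of GAPDH exceeded its 5′ probe set by 1.40 ± 0.43 on the log2 scale in failing and 3.00 ± 0.72 in non-failing hearts (SD, n = 4, exact two-sided permutation p = 0.0286). The same difference for ACTB was 2.76 ± 0.53 in failing and 4.02 ± 0.44 in non-failing hearts (exact two-sided permutation p = 0.0286). The 18S ribosomal RNA probe sets averaged 11.12 ± 0.83 in failing and 9.47 ± 0.80 in non-failing hearts (exact two-sided permutation p = 0.0571). The first principal component of the gene signals held 28.2% of the variance and separated the groups without overlap (exact two-sided permutation p = 0.0286), and the second held 22.2% (exact two-sided permutation p = 0.514). The first component also went with the GAPDH control within the groups. Among failing hearts it fell from 28.30 in heart 2 (control 0.82) to 11.05 in heart 4 (1.82). Among non-failing hearts it was highest in heart 3 (-11.64, control 1.95), against -24.35 in heart 4 (3.42) and -20.41 in heart 1 (3.49). Failure and RNA quality therefore cannot be told apart on this component. Correlations between arrays over genes, which are not independent replicates, ran from 0.978 to 0.991.

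**Figure D3:**
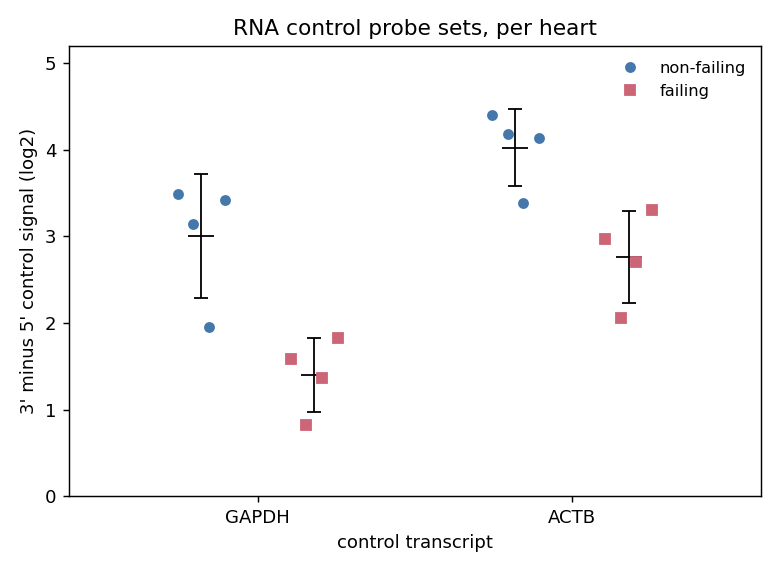
Difference between the 3′ and 5′ control probe sets (log2, vertical axis) of GAPDH and ACTB, with 1 point per heart, 4 non-failing (circles) and 4 failing (squares), and black bars for the mean ± SD. All 4 failing hearts lay below all 4 non-failing hearts for both transcripts, from 0.82 to 1.82 against 1.95 to 3.49 for GAPDH.

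With the GAPDH control difference as a covariate limma called 0 genes after Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 926 genes, where chance gives 987 on average and the fit without the covariate gave 2687. All of the 79 genes kept their direction there, with a median size of 0.99 on the log2 scale against 1.01 without the covariate and a median SE of 0.26 against 0.14. Leaving out 1 heart at a time gave between 26 genes (without non-failing heart 2) and 136 genes (without non-failing heart 3). The direction of the 79 genes could not turn there, since the groups did not overlap for any of them.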

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

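The test of macrophage list members on held-out hearts, the general macrophage genes set beside it and the fits of gene lists with the GAPDH control as a covariate were chosen only after the data were seen, the first also after its result was seen.

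Of 226 groups of 4 hearts examined, 10 held a heart far from the other 3, where chance at about 1 in 20 gives 11. Non-failing heart 4 stood apart from the other non-failing hearts on the second principal component (31.82 against -16.91 to -11.89), in the mean of the collagen and matrix list (9.81 against 8.14 to 8.32) and in the mean of the natriuretic peptide and stress list (11.50 against 10.93 to 10.96). In the same heart FRZB was at 7.57 against 6.16 to 6.40, and MYH7 at 12.34 against 12.91 to 12.96. ATP2A2 was at 13.27 in failing heart 2 against 13.44 to 13.47 in the other failing hearts, and at 13.67 in non-failing heart 3 against 13.36 to 13.37. EXT1 was at 8.75 in failing heart 4 against 8.29 to 8.34, and IL1RL1 at 7.92 in non-failing heart 2 against 7.39 to 7.47. The adipocyte list mean was 7.46 in failing heart 1 against 6.35 to 6.49. Among 13486 probe sets without a single gene symbol, which the gene comparison does not use, 11 changed.

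The macrophage markers were lower in failing hearts by a mean of -1.10 (95% interval -1.43 to -0.78). With the GAPDH 3′ minus 5′ control as a covariate the mean difference was -1.15 (95% interval -1.83 to -0.46), where RNA 3′ bias as the whole cause predicted an interval that includes 0. The control did not overlap between the groups, so this fit extends slopes seen within groups and cannot decide on RNA 3′ bias. Fewer macrophages of every kind as the whole cause would lower the members alike only if all their signal came from macrophages and lay above background. Neither was assessed. The 5 lowest of 14 members, chosen on 4 hearts and measured on the other 4, averaged -2.26 against -0.46 for the other 9. That gap of -1.79 (-2.17 to -1.41 over 36 choices of hearts) shows that unequal falls recurred in other hearts. Markers that differ in source or background would give a gap too, so fewer macrophages as the whole cause stays open. Beside it, 10 general macrophage genes, 4 of them also in the fixed macrophage list, averaged -0.54 (95% interval -1.0 to -0.08, exact two-sided permutation p = 0.0857). They ran from -1.19 (C1QB) to -0.0089 (SPI1), with 0 past the threshold in limma and 3 at an unadjusted p under 0.05. Signal near background, which was not assessed and would shrink the fall of weak probe sets, glucocorticoid exposure and the failing state itself also stay open.

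The interferon response genes were higher in failing hearts by a mean of 0.60 (95% interval 0.10 to 1.11). With the GAPDH control as a covariate the mean difference was 0.99 (95% interval 0.04 to 1.93). RNA 3′ bias as the whole cause predicted an interval that includes 0, and this one comes close to 0. The control did not overlap between the groups, so this fit too cannot decide on RNA 3′ bias. The lowest mean difference with 1 heart left out, 0.43 without failing heart 1, argues against a single heart as the whole cause. There limma's camera adjusted p was 1.11e-06, the highest of the 8 such fits, at the preset correlation of 0.01. The correlation estimated for this list was 0.26, so that p is weak support. The list mean of failing heart 1 was 8.09, against 7.29 to 7.50 in the other failing hearts. Non-failing heart 4 reached 7.25, close to the lowest failing heart. Over all alternatives of this list the adjusted p reached 0.413, with an estimated correlation. RNA 3′ bias stays open, as do the failing state and any other difference between the donor groups, which were not tested.

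The 5′ signal of GAPDH and ACTB relative to the 3′ signal was higher in failing hearts. Over 19732 genes, which are not independent replicates, the slope of each gene on the GAPDH control within the groups, times the gap between the groups, correlated with the group difference at 0.199 (one-sided exact p = 0.0122 over 576 permutations within groups, highest lower value 0.197), which is consistent with a part of the differences over all genes going with RNA 3′ bias. Among the 79 changed genes 44 had the sign this predicts, and the median predicted share of their difference was 0.0145. These genes were called for a small spread within groups against a large difference between them, which by itself keeps that share small. It therefore does not measure how much RNA 3′ bias adds to them. With the control as a covariate CD163 went from -2.93 (SE 0.27) to -2.56 (SE 0.51) and MX1 from 1.00 (SE 0.14) to 1.30 (SE 0.26), and calls ended as the median SE of the 79 genes grew from 0.14 to 0.26 while their median size went from 1.01 to 0.99. The control did not overlap between the groups, so its share in a single gene's difference stays open.

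Over the 35 splits of the 8 hearts into 4 and 4, only the real split reached the count of genes that were higher (28, with at most 1 in any other split). The same held for genes that were lower (51, with at most 1) and probe sets that changed (105, with at most 3). This is the smallest share that 35 splits allow, so it argues against chance for these counts without excluding it. For the gene lists chance stays open, since 6 of the 35 splits gave at least as many, with 9 in the real split and 9 as the highest of the others.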

How the results depend on the processing

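The fits with the mean of the GAPDH and ACTB controls as a covariate, those without non-failing heart 4 and failing heart 1 together, and the gene list fits with the GAPDH covariate were tests chosen after seeing the data. The counts of genes higher in failing hearts (28) and genes lower in failing hearts (51) became 44 and 77 with array weights, where the cause was not tested, 1 and 11 at an adjusted p under 0.01, fewer by construction, and 0 and 0 with the GAPDH control as a covariate and again with the mean control, although 74 and 75 of the 79 genes stayed at an unadjusted p under 0.05 in limma. With the replicate number as a block (replicate block) they were 9 and 30, with 29 of the 39 genes shared, and 9 lists passed. Hearts of the same number shared only that number: the 4 pairs correlated from -0.246 to 0.0435, and 0 failing hearts were closest to their own number. Leaving out 1 heart gave 5 to 87 genes higher, 19 to 67 lower, 9 to 233 probe sets changed (without failing heart 3 and non-failing heart 3) and 3 to 10 lists. Changed genes numbered 27, 26, 136 and 111 without non-failing hearts 1 to 4, and 43, 36, 32 and 46 without failing hearts 1 to 4. The other alternatives kept both gene counts within 1.5 times. Of the 9 lists 0 passed camera with an estimated correlation (3 lists at an unadjusted p under 0.05), 1 passed fry, 5 passed with the mean of all probe sets and 3 at a mean log2 signal of at least 5, and the cause was not tested. With the GAPDH covariate 12 lists passed, 5 of them shared. The 29 named genes past the threshold had 656 alternative values, 655 in the same direction and 399 past the threshold. Leaving out hearts, a stricter threshold or a minimum fold could not turn the direction of these 29, whose groups did not overlap. The 46 others had 1033 alternative values, 22 past the threshold and 13 with turned direction. Without _x_at and _s_at probe sets other probe sets stood for DPYSL3 (-0.068), SDHC (-0.058) and HBB (-0.12), which turned. With the GAPDH covariate MYH7 (-0.048), SDHC (-0.093), PLIN4 (-0.052), LIPE (-0.36), KRT8 (-0.033) and the lists of oxidative phosphorylation (-0.10), glucose use (-0.11), smooth muscle and pericyte markers (-0.43), TCA cycle (-0.12), Schwann and neural markers (-0.034) and mesothelium (-0.047) turned. With the mean control SDHC (-0.048), PLIN4 (-0.047), LIPE (-0.31) and SOX10 (-0.021) turned, and the cause was not tested. ATP2A2 ran from -0.054 to 0.051 with 1 heart left out. Means of lists that did not pass also turned with 1 heart left out. Among them were immediate early genes (-0.026 without failing heart 3) and oxidative phosphorylation (-0.021 without non-failing heart 4). Without non-failing heart 3, adipocyte markers (0.18) and fatty acid oxidation (0.026) turned as well. Signal over background was not assessed, so differences of weak probe sets may be understated.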

Other observations

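Changed genes outside the fixed lists included those below, single genes chosen after their values were seen, with no test of a gene group behind them. RNASE6, a ribonuclease of myeloid cells, was at -1.34 (SE 0.20, n = 4 hearts per group, limma adjusted p = 0.0278) and EVI2B, a membrane protein of leukocytes, at -1.26 (SE 0.19), each with 1 probe set. ITGAM, the integrin alpha chain of complement receptor 3, was at -1.41 (SE 0.22, limma adjusted p = 0.0312) on a probe set that may cross-hybridize, and at 0.083 on its other probe set. BST2, which tethers enveloped viruses to the cell surface, was at 0.68 (SE 0.10, limma adjusted p = 0.0302). PARP14, an ADP-ribosyltransferase, was at 0.72 (SE 0.09, limma adjusted p = 0.0178), and at -0.085 on its other probe set.

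AASS, which begins the breakdown of lysine, was at -1.22 (SE 0.13, limma adjusted p = 0.00785), and at -0.84 on its other probe set. GLUL, glutamine synthetase, was at -0.86 (SE 0.13), with -0.62 to -1.40 on its other probe sets. CTH, which makes cysteine from cystathionine, was at -0.95 (SE 0.16, limma adjusted p = 0.0483), and at -0.25 on its other probe set. The alcohol dehydrogenase ADH1B was at -1.67 (SE 0.24), with -2.13 to -0.015 on its other probe sets, and GRB14, an adaptor protein that inhibits insulin receptor signalling, at -1.50 (SE 0.12, limma adjusted p = 0.00258). On the probe set tested for each gene of both paragraphs, the 4 failing hearts lay on one side of the 4 non-failing hearts.

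FKBP5, CD163 and SERPINA3, which glucocorticoids are known to induce, were all lower in failing hearts, so a hypothesis formed after these values were seen is that glucocorticoid exposure of the non-failing hearts may account for part of the macrophage decrease. It was tested on 15 other glucocorticoid-induced genes, listed before their differences were looked at, 4 of which also stand in fixed lists other than the macrophage markers. Their mean was 9.85 ± 0.20 (SD, n = 4) in failing and 10.27 ± 0.23 in non-failing hearts, a difference of -0.43 (95% interval -0.80 to -0.06, exact two-sided permutation p = 0.0857), and 13 of the 15 were lower. In limma 0 of them passed after adjustment, with 7 lower and 0 higher at an unadjusted p under 0.05, and with the GAPDH control as a covariate the difference was -0.55 (95% interval -1.32 to 0.23). The exact test did not pass. Exposure of the non-failing hearts would go with the groups, so even a test that passed could not tell the hypothesis from the failing state in these 8 hearts. Treatment of the donors was not used here.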
